A study of Homo sapiens with 15 samples.

How the data were processed

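Gene expression was measured on 15 Affymetrix arrays of MCF7, a human breast cancer cell line that expresses the estrogen receptor. The RNA came from cultured cells or from xenografts grown in nude mice. Some of the cultured cells had received a retrovirus with an active form of RAF1, the kinase at the head of the MEK and ERK cascade. Per the labels, total RNA was extracted with a Qiagen kit and turned into biotinylated cRNA by the Affymetrix protocol. The labels placed the arrays in 8 groups. There were 2 arrays each for wild type, first generation, RAF1, lung metastasis, visceral metastasis, CD24 high and CD24 low cells, and 1 array for RAF1 first generation cells. Arrays of a group were numbered here in the order in which they are listed. The meaning of first generation is not given in the labels, and neither is the origin of the CD24 cells or of the cells that formed the metastases. The CD24 arrays carried a title prefix of their own, apart from the prefix shared by the other 11, so the CD24 groups were tested only against each other. A single check of explanations, given in the closing section, also set CD24 high beside RAF1 and wild type.

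The deposited values are log2 expression values, 1 per probe set. The submitters' processing notes name GCRMA and Partek; their versions are not given in the sources used here. GCRMA gives log2 summaries after a background correction that uses probe sequence, and no further scaling was applied for the comparisons. At most 1.14% of values were identical between any pair of arrays, so no array was a copy of another.

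The table held 54675 probe sets. Of these, 41097 carried 1 gene symbol, 1801 carried several and 11777 carried none, and only the first kind was used. Gene identifiers of 41043 probe sets matched the RefSeq gene table of assembly GRCh38.p14, which gave chromosome positions. Each of 19775 genes was represented by its probe set of highest mean over the 15 arrays. A gene was tested where at least 1 array reached log2 5, which left 11153 genes. RAF1 itself had no probe set named in the probe table and was not analysed here.

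Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The model had a mean per group over all 15 arrays, with moderated variances (eBayes with trend and robust). It had 7 residual degrees of freedom, and prior degrees of freedom ran from 2.4 to 2.63. The group with 1 array was assumed to vary like the others. There were 11 comparisons. P-values were adjusted by the method of Benjamini and Hochberg over the genes of a comparison, and a gene passed under an adjusted p of 0.05. The labels do not say whether arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these arrays. The small number of arrays limits the precision of every value.

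The comparisons, the test, the filter, the gene lists and the alternatives were fixed before the data were examined. A gene was named when it passed the test, had a mean of at least 6 in the higher group and did not overlap between the arrays of the groups compared. Overlap was not asked of the interaction. The 10 largest differences in each direction qualified, and up to 4 members that passed the test were named per list. RAF1 and CD24 were fixed in advance, and uncharacterised transcripts were left out. Because many genes lay near background in one of the groups, the size of such a difference depends on the floor, and some are also given with all values under 4 set to 4.

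There were 27 gene lists, tested with limma camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. They covered ERK pathway output, ErbB receptors and ligands, estrogen response, luminal identity, basal and stem cell markers, mesenchymal transition, epithelial junctions, cell cycle, centrosome and mitotic kinases, interferon response, class I antigen presentation, inflammatory cytokines, matrix and proteases, hypoxia and glycolysis, unfolded protein response, cholesterol synthesis, p53 targets, immediate early and stress genes, cytosolic ribosomal proteins and oxidative phosphorylation. A further 7 lists held markers of fibroblasts, endothelium, leukocytes, erythroid cells, lung epithelium, liver and gut, and adipocytes. Camera compares a list with all other genes, so its direction can differ from the sign of the list's own mean. The smallest lists tested held 3 genes.

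The fit was tested on simulated data drawn with the mean and residual SD of each gene and no correlation between genes, with 200 changed genes. In RAF1 against wild type it recovered 7.5% of genes changed by a log2 difference of 1, 53.7% at 2 and 81.8% at 4, and it called 8 unchanged genes. With the smaller residual SDs of 14 arrays, a simulated rise of 1 in the interferon list of RAF1 against wild type was found at adjusted p = 1.19e-07, and 0 of the 25 other lists were called.

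CD24 low array 2 stood apart from the other 14 arrays. A fit of those 14 arrays was added after the data were seen, and its count is given beside each comparison. The alternatives fixed in advance were array weights, every probe set, the mean of a gene's probe sets, a filter on a mean of at least 5, no filter, median centring, quantile scaling, the arrays of the shared title prefix alone, the groups of a contrast alone, no trend or robust option, no moderation, values under 4 set to 4, a 2-fold limit, and each array left out in turn.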

Results

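The arrays asked how an active RAF1 kinase changes MCF7 breast cancer cells, and how cells recovered from lung and visceral metastases of nude mice differ from those cells. Values are mean log2 expression ± SD with n = 2 unless stated, and differences are in log2 with a standard error (SE). Genes were placed on assembly GRCh38.p14. Of the genes drawn by array, TM4SF1 (gene identifier 4071) lies on chromosome 3 at 149369022 to 149377649, PLS3 (5358) on X at 115561174 to 115650861 and NUPR1 (26471) on 16 at 28532708 to 28538974. CA2 (760) lies on chromosome 8 at 85464007 to 85481493, AGR2 (10551) on 7 at 16791811 to 16804999 and SERPINA5 (5104) on 14 at 94581426 to 94593118. PYCARD (29108) lies on chromosome 16 at 31201486 to 31202760, TGFB2 (7042) on 1 at 218345336 to 218444619 and PGR (5241) on 11 at 101029624 to 101129813. Between arrays of a group the correlation across probe sets was 0.997 in wild type, 0.998 in visceral metastasis and in CD24 high, 0.989 in RAF1, 0.987 in first generation and in lung metastasis, and 0.922 in CD24 low.

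**Figure D1:**
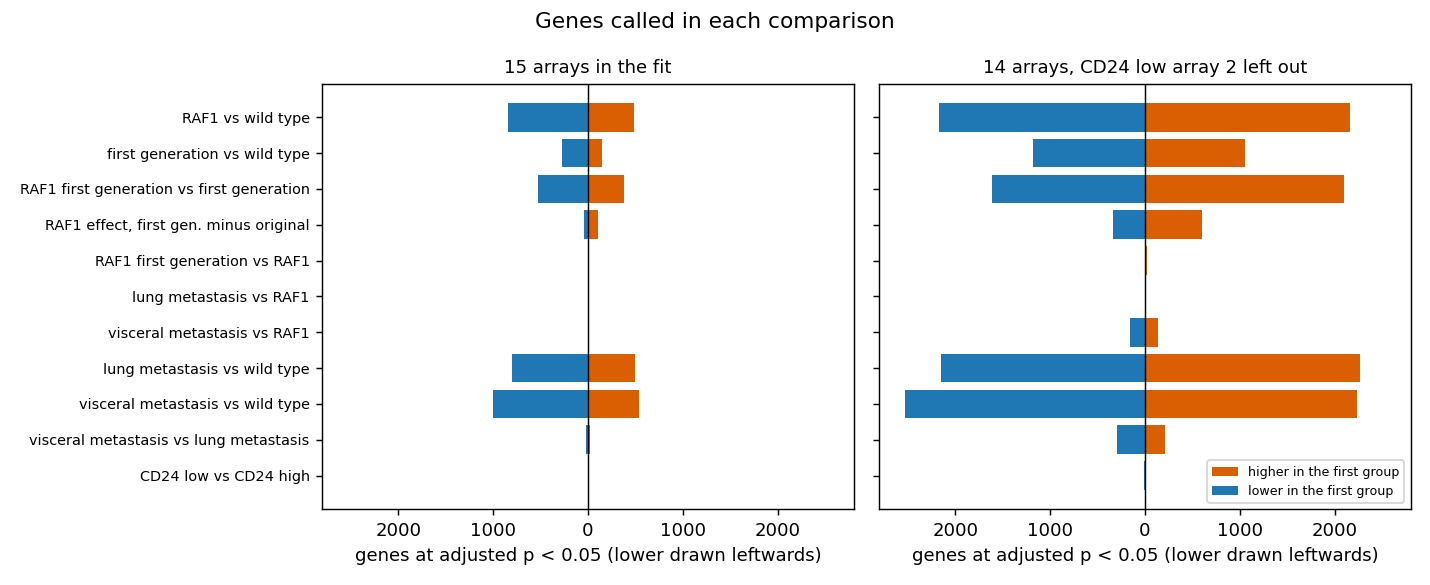
Genes called higher and lower in each comparison, from the fit of 15 arrays and from the fit of 14 arrays. The fit of 14 arrays leaves out CD24 low array 2 and was chosen after the data were seen.

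RAF1 cells were compared with wild type MCF7 cells. TM4SF1, a membrane protein of migrating cells, rose from 4.03 ± 0.65 to 13.04 ± 0.29, a difference of 9.01 (SE 1.3, adjusted p = 0.00202). PLS3, an actin bundling protein, rose from 2.67 ± 0.11 to 11.56 ± 0.01, a difference of 8.89 (SE 0.65, adjusted p = 2.83e-05). CA2, a carbonic anhydrase, fell from 12.88 ± 0 to 2.28 ± 0.01, a difference of −10.6 (SE 0.46, adjusted p = 2.42e-06). Wild type cells expressed AGR2, a protein disulfide isomerase induced by estrogen, at 14.87 ± 0.03, and RAF1 cells at 7.44 ± 1.86 (difference −7.43, SE 0.68, adjusted p = 0.000136). With values under 4 set to 4 the differences were 8.79 for TM4SF1, 7.56 for PLS3, −8.88 for CA2, 7.64 for WDR72 and −5.61 for PYCARD.

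In RAF1 cells, further genes rose from near background. The stress-induced cofactor NUPR1 went from 4.36 ± 0.02 to 11.56 ± 2.35 (difference 7.2, adjusted p = 0.00348), and the epithelial transcription factor EHF rose by 5.86 (adjusted p = 0.00019). WDR72 rose by 8.42, the cadherin FAT1 by 5.87 and the homeobox gene HOXC10 by 5.46. Among genes that fell, SERPINA5, a protease inhibitor, changed by −8.02 (SE 0.23, adjusted p = 1.58e-07), and AGR3 by −8.16 (SE 0.8, adjusted p = 0.000193). PYCARD, the adaptor of the inflammasome, fell from 9.61 ± 0.11 to 2.05 ± 0.03, a difference of −7.56 (SE 0.37, adjusted p = 2.84e-06). The antigen CT83 fell by 8.31, the acute phase inhibitor SERPINA3 by 8.47 and the matrix protein MGP by 7.43. CD24, a luminal surface marker, differed by −1.14 (SE 0.45) and did not pass (adjusted p = 0.15), but passed with 14 arrays (adjusted p = 0.00638), array weights, the shared title prefix, the groups of the contrast alone, median centring and quantile scaling (adjusted p from 0.000313 to 0.0253).

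**Figure D2:**
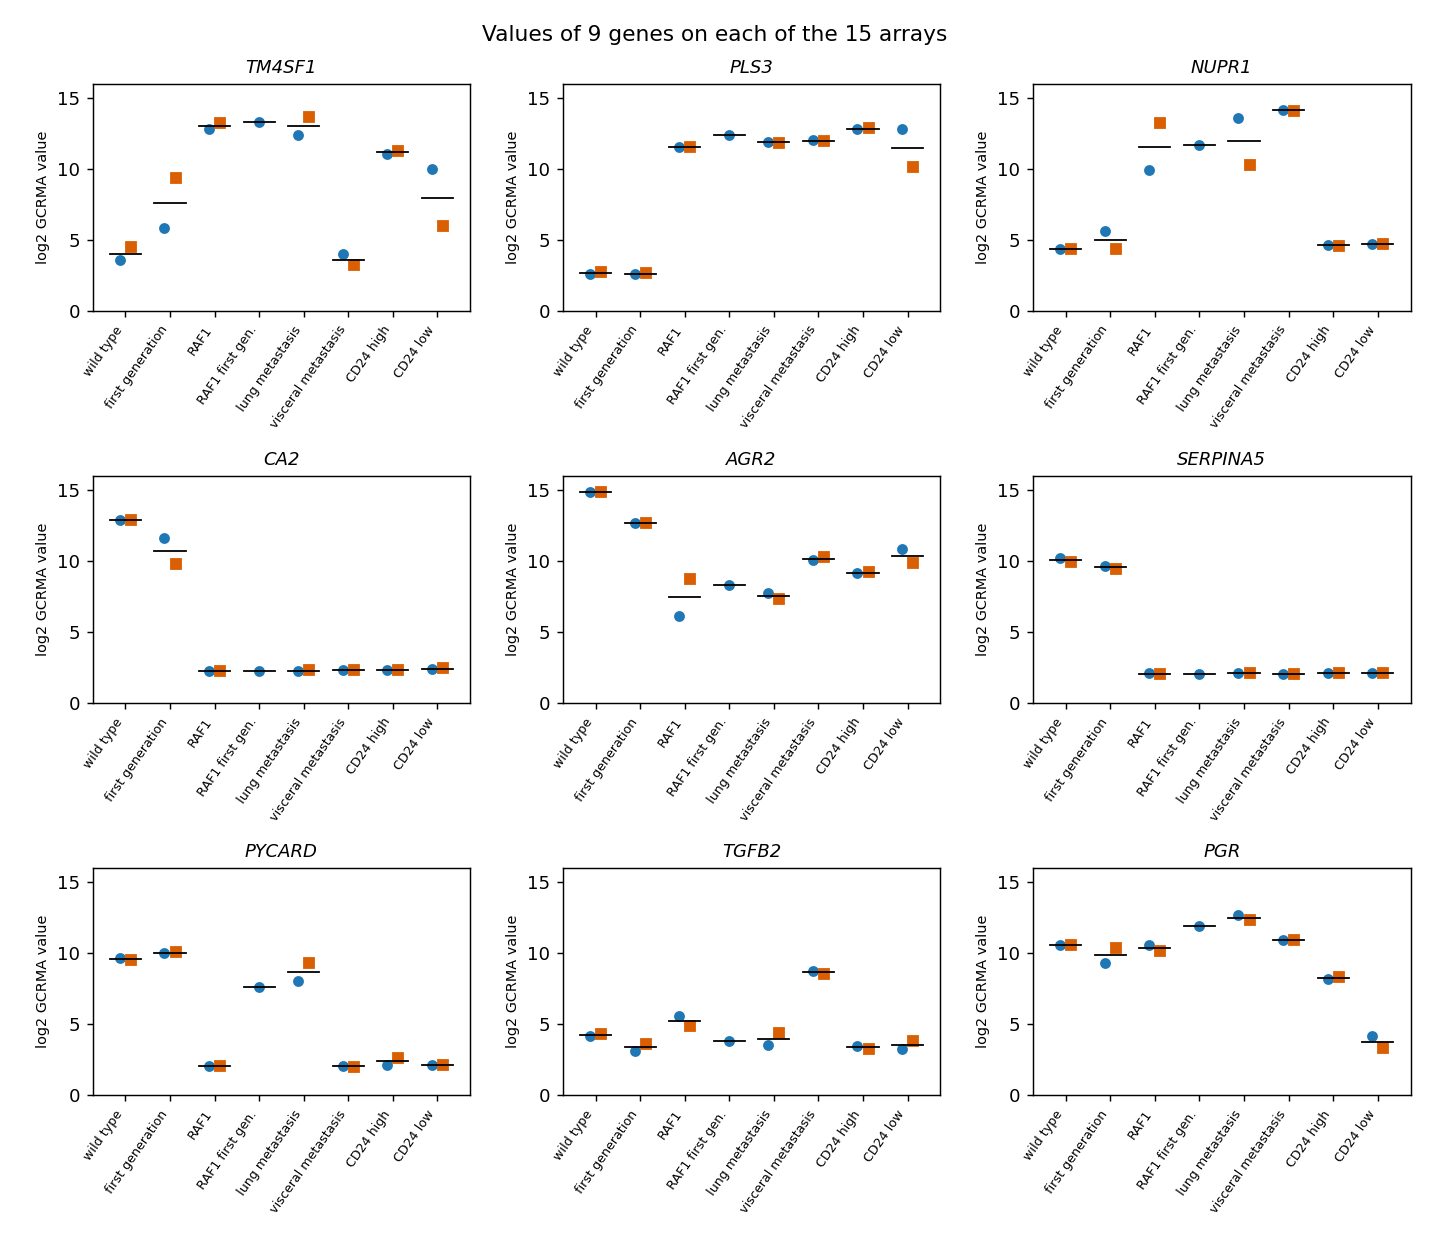
Log2 expression of 9 genes on each array. Circles are replicate 1, squares are replicate 2, and lines are group means.

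Among 27 estrogen response genes, 8 fell in RAF1 cells, 1 rose and 18 did not pass (list adjusted p = 1.89e-05). The fallers included AGR3, AGR2, PDZK1 at −5.55 and SERPINA1 at −4.6. The list lost its call (adjusted p = 0.452 with an estimated correlation). Of 14 basal and stem cell markers, 7 fell, 0 rose and 7 did not pass, and 8 fell when adjusted over the list alone. They included the stem cell factor SOX2 at −6.56, the ecto-enzyme NT5E at −5.34, SOX9 at −3.91 and the integrin ITGB4 at −3.25. This list kept its call both ways (adjusted p = 8.01e-06, and adjusted p = 0.032 with an estimated correlation). Adipocyte markers fell at 2 of 3, the fatty acid transporter CD36 at −7.05 and PPARG at −3.46 (list adjusted p = 0.000229, adjusted p = 0.0575 with an estimated correlation).

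Cytosolic ribosomal proteins rose in RAF1 cells at 10 of 27 genes, with 0 lower and 17 not passed, and at 13 when adjusted over the list alone. RPL19 rose by 1.13, RPS9 by 1.09 and RPL3 by 1.05, and RPL3 lost its call after median centring (adjusted p = 0.121). The list was called at adjusted p = 2.46e-08 and lost its call (adjusted p = 0.365 with an estimated correlation). Of 32 interferon response genes, 3 fell, 0 rose and 29 did not pass (list adjusted p = 6.93e-06, adjusted p = 0.711 with an estimated correlation). The fallers were the immunoproteasome subunits PSMB8 at −4.88 and PSMB9 at −4.23, and the exonuclease ISG20 at −4.88. The RAF1 replicates differed here, with list means of 5.51 and 9.2 against 9.91 and 9.92 in wild type. Antigen presentation fell at 4 of 17 genes and rose at 0, with 13 not passed and 7 lower when adjusted over the list alone (list adjusted p = 0.000693, adjusted p = 0.452 with an estimated correlation). HLA-C fell by 2.68 and B2M by 1.11.

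Matrix and protease genes fell at 6 of 23, rose at 0 and did not pass at 17, among them the protease inhibitors TIMP2 at −3.83 and TIMP1 at −2.88 (list adjusted p = 0.00696, adjusted p = 0.365 with an estimated correlation). Hypoxia and glycolysis genes fell at 5 of 32, with 0 higher and 27 not passed, including the collagen hydroxylase P4HA2 at −2.7 and the enolase ENO2 at −2.09 (list adjusted p = 0.00386, adjusted p = 0.71 with an estimated correlation). Cholesterol synthesis fell at 2 of 19, TM7SF2 by 1.31 and NSDHL by 1.26, with 0 higher and 17 not passed (list adjusted p = 0.0052, adjusted p = 0.75 with an estimated correlation).

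ERK pathway output, the list nearest to RAF1 itself, was not called (adjusted p = 0.682). In it, 2 of 20 genes rose, 3 fell and 15 did not pass. The feedback inhibitor SPRY1 rose by 2.33, and the ERK phosphatase DUSP4 changed by −3.31, the receptor EPHA4 by −3.22 and the inhibitor SPRED1 by −2.79. Of 8 ErbB receptors and ligands, BTC rose by 2.18, EGFR fell by 2.61 and 6 did not pass (adjusted p = 0.682). Luminal identity had 2 of 19 higher and 5 lower, with 12 not passed (adjusted p = 0.266), including the adhesion protein CEACAM6 at −5.77 and the transcription factors TFAP2A at 4.27 and SPDEF at 1.7. Mesenchymal transition had 1 of 12 higher, CCN1 at 3.05, and 4 lower, with 7 not passed (adjusted p = 0.111). The fibronectin gene FN1 changed by −5.08, TGFBI by −4.81 and the cadherin CDH11 by −4.69.

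The other lists were not called in RAF1 cells. In the cell cycle list 1 of 32 fell, the transcription factor E2F1 at −1.82 (adjusted p = 0.955), and in the centrosome list 1 of 28, PLK2 at −2.58 (adjusted p = 0.065). The p53 targets had 0 of 22 in either direction (adjusted p = 0.955). Immediate early genes rose at 3 of 23, IER3 by 2.17, JUNB by 1.58 and IER2 by 1.28 (adjusted p = 0.439).

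Markers of other cell types stayed uncalled in RAF1 cells apart from the adipocyte list. Leukocyte markers had 2 of 4 lower, the actin regulator CORO1A at −5 and HLA-DRB1 at −1.27 (adjusted p = 0.0834). Lung epithelium was not called (adjusted p = 0.955), nor liver and gut (adjusted p = 0.458). Of 11 erythroid markers 6 were on the array and 0 reached the filter. The median, mean and test differed in sign for epithelial junctions, unfolded protein response, p53 targets, immediate early genes and lung epithelium.

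RAF1 against wild type gave 1320 genes, 482 higher and 838 lower, and 4336 in the fit of 14 arrays (2160 higher, 2176 lower). After median centring the split was 830 higher and 908 lower. Without RAF1 array 1 or 2 the count was 638 or 782, and without wild type array 1 or 2 it was 492 or 490. EPHA4, SPRY1, SPDEF, NSDHL, JUNB, IER2 and HLA-DRB1 lost their calls with any of these 4 arrays left out (adjusted p from 0.0516 to 0.243). The calls of DUSP4, HLA-C, B2M, P4HA2 and TM7SF2 ended without RAF1 array 1, wild type array 1 or 2 (adjusted p from 0.0953 to 0.278). SOX9 lost its call without RAF1 array 2, wild type array 1 or 2 (adjusted p from 0.0627 to 0.0746). The call of E2F1 ended without RAF1 array 1 or wild type array 1 (adjusted p from 0.0596 to 0.08). RPL3 lost its call without RAF1 array 1 or wild type array 2 (adjusted p from 0.0717 to 0.0857). The call of BTC ended without RAF1 array 2 or wild type array 1 (adjusted p from 0.0812 to 0.128). EGFR lost its call without wild type array 2 (adjusted p = 0.0526).

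First generation cells, for which the labels name no introduced gene, were compared with wild type. DMD, the dystrophin gene, rose from 2.59 ± 0 to 9.77 ± 1.43, a difference of 7.18 (SE 0.54, adjusted p = 6.76e-05). PLAT, the tissue plasminogen activator, rose from 3.38 ± 0.49 to 9.36 ± 0.21, a difference of 5.99 (SE 0.37, adjusted p = 2.05e-05). The potassium channel subunit KCNE4 rose by 6.84 (SE 0.42, adjusted p = 2.08e-05). CT83, a cancer testis antigen, fell from 10.63 ± 0.21 to 2.35 ± 0.02, a difference of −8.28 (SE 0.25, adjusted p = 3.27e-07).

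Other large rises were in the gap junction gene GJA1 at 6.42, the neurotrophin receptor NTRK2 at 6.19, FAT1 at 5.9, the potassium channel KCNK2 at 5.8 and the transcription factor DACH1 at 5.35. Among the fallers were MGP at −6.22, the melanosome enzyme TYRP1 at −6.19, the annexin ANXA1 at −5.84, the kinase CAMK2D at −5.35 and S100A7 at −5.18. CD24 differed by 0.37 (adjusted p = 0.894).

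Cell cycle genes fell at 7 of 32 in first generation cells, rose at 0 and did not pass at 25, and 8 fell when adjusted over the list alone (list adjusted p = 6.04e-10). The transcription factor MYBL2 changed by −2.98, CDC45 by −2.69, E2F1 by −2.12 and the thymidylate synthase TYMS by −1.97. The call was lost (adjusted p = 0.508 with an estimated correlation), and the first generation arrays differed, with list means of 9.88 and 7.9 against 10.33 and 10.27 in wild type. The centrosome list had 0 of 28 genes past the test and was called lower (adjusted p = 0.0107, adjusted p = 0.786 with an estimated correlation), with first generation arrays at 9.4 and 7.86 on either side of wild type at 9.2 and 9.29.

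Interferon response genes fell at 3 of 32, rose at 0 and did not pass at 29, while 16 fell and 1 rose when adjusted over the list alone. PSMB9 changed by −5.12, PSMB8 by −4.89 and the antiviral RSAD2 by −2.9. The list was called at adjusted p = 6.4e-12 (adjusted p = 0.508 with an estimated correlation), with means of 5.91 and 7.63 on the first generation arrays. Antigen presentation fell at 2 of 17 genes, rose at 0 and did not pass at 15 (list adjusted p = 0.003, adjusted p = 0.508 with an estimated correlation).

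ERK pathway output fell at 3 of 20 genes, rose at 1 and did not pass at 16, and 7 fell when adjusted over the list alone (list adjusted p = 0.00199, adjusted p = 0.0793 with an estimated correlation). MAFF fell by 3.34, SPRED1 by 2.95 and EGR3 by 2.44, while IER3 rose by 1.82. Immediate early genes fell at 4 of 23, rose at 1 and did not pass at 18, with FOSB at −4.18 and ATF3 at −3.29 (list adjusted p = 0.000482, adjusted p = 0.426 with an estimated correlation). Mesenchymal transition fell at 3 of 12, rose at 0 and did not pass at 9 (list adjusted p = 0.00289, adjusted p = 0.145 with an estimated correlation). Its fallers were the connective tissue growth factor CCN2 at −5.7, FN1 at −5.08 and CCN1 at −3.06, and the list call ended without the expression filter (adjusted p = 0.0797).

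Adipocyte markers fell at 2 of 3 in first generation cells, CD36 by 4.2 and PPARG by 3.45, and the list kept its call both ways (adjusted p = 1.54e-05, adjusted p = 0.0497 with an estimated correlation). Leukocyte markers fell at 1 of 4, CORO1A by 1.89, with 0 higher (list adjusted p = 0.003, adjusted p = 0.101 with an estimated correlation). Ribosomal protein genes had 0 of 27 past the test and were called higher as a list (adjusted p = 0.0338, adjusted p = 0.786 with an estimated correlation). That call ended after median centring (adjusted p = 0.285). Estrogen response was not called (adjusted p = 0.073), with AGR3 at −5.15, PDZK1 at −4.9, the trefoil factor TFF3 at 3.05 and ABCA3 at 1.74. The remaining lists were not called, and luminal identity, lung epithelium, and liver and gut had a median, mean and test that differed in sign.

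First generation against wild type gave 423 genes, 151 higher and 272 lower, and 2236 in the fit of 14 arrays (1053 higher, 1183 lower). Without wild type array 1 or 2 the count was 153 or 134, and without first generation array 1 or 2 it was 371 or 357. The calls of CCN2 and RSAD2 ended with any of these 4 arrays left out (adjusted p from 0.0516 to 0.232). MAFF, TFF3, ATF3 and CORO1A lost their calls without first generation array 1, wild type array 1 or 2 (adjusted p from 0.0724 to 0.157). The calls of MGP, ABCA3 and MYBL2 ended without first generation array 2, wild type array 1 or 2 (adjusted p from 0.059 to 0.169). EGR3, AGR3, CDC45 and TYMS lost their calls without wild type array 1 or 2 (adjusted p from 0.0634 to 0.0962). The call of E2F1 ended without wild type array 1 (adjusted p = 0.0887).

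First generation cells with RAF1 were measured on 1 array, so values of that group have no SD. PLS3 stood at 12.35 on that array against 2.63 ± 0.02 in first generation cells, a difference of 9.72 (SE 0.79, adjusted p = 0.000118). WDR72, which is needed for enamel formation, stood at 12.59 against 2.17 ± 0.01, a difference of 10.42 (SE 0.9, adjusted p = 0.000165). With values under 4 set to 4 these were 8.35 and 8.59. CA2 fell from 10.72 ± 1.29 to 2.27, a difference of −8.45, or −6.72 with that floor (SE 0.57, adjusted p = 4.54e-05). The microtubule-linked kinase DCLK1 fell from 11.37 ± 0.24 to 3.44, a difference of −7.94 (SE 0.31, adjusted p = 9.88e-07).

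The cytokine TNFSF15 rose by 8.57, EHF by 7.49, CCN2 by 6.88 and NUPR1 by 6.68. SERPINA5 fell by 7.5 (SE 0.29, adjusted p = 9.88e-07), the protocadherin PCDH10 by 7.9, the pseudokinase TRIB2 by 7.65, the chemokine CXCL14 by 7.64 and the monoamine oxidase MAOB by 7.6. CD24 differed by −1.29 (adjusted p = 0.213) and passed with 14 arrays (adjusted p = 0.0116), array weights, the shared title prefix, median centring and quantile scaling (adjusted p from 0.00132 to 0.032).

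Cholesterol synthesis fell at 5 of 19 genes with RAF1, rose at 0 and did not pass at 14, and 10 fell when adjusted over the list alone. The enzymes MVD at −3.47, LSS at −3.05, IDI1 at −2.69 and DHCR7 at −2.07 were among them (list adjusted p = 2.81e-06, adjusted p = 0.57 with an estimated correlation). The first generation arrays lay apart at 11.17 and 9.91, against 8.75 with RAF1. Basal and stem cell markers fell at 5 of 14, rose at 0 and did not pass at 9 (list adjusted p = 0.000373, adjusted p = 0.0952 with an estimated correlation), including SOX2 at −3.87, SOX9 at −3.84 and ITGB4 at −3.81. Matrix and protease genes fell at 5 of 23, rose at 2 and did not pass at 16, with PLAT at −6.93, TIMP2 at −4.56 and the protease inhibitor SERPINE2 at 3.1 (list adjusted p = 0.00207, adjusted p = 0.46 with an estimated correlation). Hypoxia and glycolysis fell at 2 of 32, ENO2 by 2.68 and PKM by 1.45, with 0 higher (list adjusted p = 0.0137, adjusted p = 0.595 with an estimated correlation).

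Luminal identity fell at 3 of 19, rose at 0 and did not pass at 16, with CEACAM6 at −4.83, AGR2 at −4.4 and the keratin KRT19 at −0.97. The list call at adjusted p = 0.018 was lost (adjusted p = 0.57 with an estimated correlation) and in the fit of 14 arrays (adjusted p = 0.0876). Estrogen response was not called (adjusted p = 0.104), though 5 of 27 fell and 2 rose, with SERPINA1 at −5.79, the receptor RET at −4.24 and TFF3 at −3.63.

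Cell cycle genes rose at 3 of 32 with RAF1, fell at 0 and did not pass at 29, with the helicase subunits MCM7 at 1.88 and MCM3 at 1.5 and TYMS at 1.72 (list adjusted p = 2.37e-05, adjusted p = 0.57 with an estimated correlation). The first generation arrays it was compared with had list means of 9.88 and 7.9, and the RAF1 first generation array 10.43. The centrosome list was called higher (adjusted p = 0.000624, adjusted p = 0.57 with an estimated correlation), with 0 of 28 higher and PLK2 lower at −3.41. Immediate early genes rose at 4 of 23, fell at 0 and did not pass at 19, and 9 rose when adjusted over the list alone, including ATF3 at 4.18, EGR1 at 3.98 and FOSB at 2.31. Their list call at adjusted p = 0.0249 was lost (adjusted p = 0.57 with an estimated correlation), in the fit of 14 arrays (adjusted p = 0.0979) and after median centring (adjusted p = 0.0513).

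Ribosomal proteins rose at 1 of 27, RPL19 by 0.92 (adjusted p = 0.232 after median centring), and at 6 when adjusted over the list alone (list adjusted p = 0.000244, adjusted p = 0.57 with an estimated correlation). After median centring the ribosomal list was not called (adjusted p = 0.142). ERK pathway output rose at 5 of 20 genes, fell at 0 and did not pass at 15, with MAFF at 4.62, SPRED1 at 2.58 and MYC at 2.41, and the list was not called (adjusted p = 0.0891). Other lists were not called, and ErbB receptors, interferon response, antigen presentation, unfolded protein response and p53 targets had a median, mean and test that differed in sign.

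RAF1 first generation against first generation gave 906 genes, 376 higher and 530 lower, and 3717 in the fit of 14 arrays (2100 higher, 1617 lower). Without first generation array 1 or 2 the count was 853 or 588. RET, SOX9 and SERPINE2 lost their calls without first generation array 1 or 2 (adjusted p from 0.0723 to 0.121). The calls of MVD, LSS, IDI1, DHCR7 and FOSB ended without first generation array 1 (adjusted p from 0.0632 to 0.133). CCN2, NUPR1, AGR2, CEACAM6, KRT19, MCM7, TYMS, MCM3 and PKM lost their calls without first generation array 2 (adjusted p from 0.0504 to 0.16). With only the arrays of these groups fitted 0 genes passed and all 68 named calls ended (adjusted p from 0.0788 to 0.301), so the calls and the overlap below rest on the spread within other groups. This comparison shared no array with RAF1 against wild type. Of the genes called, 171 were higher in both and 316 lower in both, where independent sets would share 16.2 and 39.8. Both sets used the same variance of each gene, which can raise the overlap. Of 504 genes called in both comparisons, 487 had the same direction, and over all 11153 genes the differences, whether called or not, correlated at 0.64.

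The interaction asked whether the difference between cells with and without RAF1 was itself different in first generation and in wild type cells. The dystrophin gene DMD had an interaction of −7.21 (SE 0.85, adjusted p = 0.00258), because it was high in first generation cells at 9.77 ± 1.43 and at 2.53 with RAF1. PLAT, the plasminogen activator, had −6.02 (SE 0.59, adjusted p = 0.000979). PDZK1, an estrogen-induced scaffold protein, had 6.93 (SE 0.57, adjusted p = 0.000589). MGP, a calcification inhibitor, had 11.29 (SE 1.69, adjusted p = 0.0104), falling with RAF1 in wild type cells and standing higher with RAF1 in first generation cells.

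The genes CT83 at 8.28, S100A7 at 8.2 and PLBD1 at 5.86 were high in wild type cells and low in first generation cells without RAF1. The dioxin-induced enzyme CYP1A1 had −8.64, GJA1 −7.34, KCNE4 −6.86, NTRK2 −6.2, FAT1 −6.19 and DACH1 −5.37. CD24 had −0.15 (adjusted p = 1).

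Interferon response was higher in the interaction at 2 of 32 genes, PSMB9 at 7.5 and PSMB8 at 4.87, with 0 lower and 30 not passed (list adjusted p = 0.000145, adjusted p = 0.744 with an estimated correlation). The RAF1 replicates differed for this list, at 5.51 and 9.2. Antigen presentation had 2 of 17 higher and 0 lower (list adjusted p = 0.000547, adjusted p = 0.581 with an estimated correlation). Cell cycle had 0 of 32 past the test over all genes and 6 higher when adjusted over the list alone (list adjusted p = 3.22e-06, adjusted p = 0.744 with an estimated correlation), and the first generation arrays lay apart at 9.88 and 7.9. Mesenchymal transition had 1 of 12 higher, FN1 at 5.79 (list adjusted p = 0.00327, adjusted p = 0.202 with an estimated correlation). Adipocyte markers had 2 of 3 higher, CD36 at 4.16 and PPARG at 3.45 (list adjusted p = 3.58e-05, adjusted p = 0.0549 with an estimated correlation).

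ERK pathway output had 1 of 20 higher in the interaction, SPRED1 at 5.37, and 1 lower, IER3 at −1.94 (list adjusted p = 0.0191, adjusted p = 0.202 with an estimated correlation). Estrogen response had 1 of 27 higher, PDZK1, and 1 lower, ABCA3 at −2.49 (list adjusted p = 0.0115, adjusted p = 0.744 with an estimated correlation). Cholesterol synthesis was called lower, by a mean of −0.83, with 0 of 19 past the test (list adjusted p = 0.00327, adjusted p = 0.744 with an estimated correlation). Its first generation arrays lay apart at 11.17 and 9.91, and its RAF1 arrays at 9.5 and 8.91. The other lists were not called, and among them ErbB receptors, unfolded protein response, p53 targets, fibroblast and endothelial markers had a median, mean and test that differed in sign.

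The interaction gave 149 genes, 107 higher and 42 lower, and 934 in the fit of 14 arrays (599 higher, 335 lower). Without wild type array 1 or 2 the count was 90 or 71. Without RAF1 array 1 or 2 it was 107 or 110, and without first generation array 1 or 2 it was 208 or 174. The calls of FAT1 and ABCA3 ended without first generation array 2, RAF1 array 1, RAF1 array 2, wild type array 1 or 2. NTRK2 lost its call without RAF1 array 1, RAF1 array 2, wild type array 1 or 2. IER3 lost its call without wild type array 1 or 2, and MGP without wild type array 2. Median centring ended the calls of NTRK2, IER3, ABCA3, CD36 and PPARG.

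With RAF1 present, few genes passed the test between first generation and original cells. PYCARD, the inflammasome adaptor, was at 7.65 on the RAF1 first generation array and at 2.05 ± 0.03 in RAF1 cells, a difference of 5.6, or 3.65 with values under 4 set to 4 (SE 0.45, adjusted p = 0.00373). The netrin NTN4 was higher by 4.13 (adjusted p = 0.0133), the zinc-binding glycoprotein AZGP1 by 3.88 and the Rho inhibitor ARHGDIB by 3.43. The ERK inhibitor SPRED1 was higher by 2.41 (SE 0.32, adjusted p = 0.0352), the only one of 20 ERK pathway output genes past the test. The growth factor binding protein IGFBP3 was higher by 2.92 and PSG9 by 3.16, while CD24 differed by 0.22 (adjusted p = 1).

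In this pair 4 lists were called lower with 0 members past the test. Cholesterol synthesis had a mean difference of −0.46 over 19 genes (list adjusted p = 0.00447, adjusted p = 0.989 with an estimated correlation), and immediate early genes −0.4 over 23 (list adjusted p = 0.00447, adjusted p = 0.884 with an estimated correlation). Interferon response had −0.87 over 32 genes (list adjusted p = 0.00494, adjusted p = 0.989 with an estimated correlation), with 6.49 on the RAF1 first generation array between the RAF1 arrays at 5.51 and 9.2. Lung epithelium markers had −0.71 over 4 genes (list adjusted p = 0.0248, adjusted p = 0.659 with an estimated correlation). In the fit of 14 arrays the interferon and lung epithelium calls ended (adjusted p = 0.0712 for both), and median centring also ended the lung epithelium call (adjusted p = 0.161). Another 9 lists, none of them called, had a median, mean and test that differed in sign, namely ERK pathway output, luminal identity, epithelial junctions, cell cycle, centrosome, hypoxia, endothelial, adipocyte and ribosomal genes.

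RAF1 first generation against RAF1 gave 9 genes, all higher, and 23 in the fit of 14 arrays (19 higher, 4 lower). Without RAF1 array 1 or 2 the count was 3 or 2. NTN4, AZGP1, ARHGDIB, PSG9, IGFBP3 and SPRED1 lost their calls without RAF1 array 1 or 2 (adjusted p from 0.0716 to 0.19). After median centring or quantile scaling the count was 1, and NTN4 did not pass (adjusted p = 0.433 and adjusted p = 0.0619). With only the arrays of these groups fitted 0 genes passed, and all 7 named calls ended (adjusted p from 0.199 to 0.677).

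Between cells harvested from lung metastases and RAF1 cells, 1 gene passed the test. PYCARD, which links inflammasome sensors to caspase 1, was at 8.66 ± 0.89 in lung metastasis and 2.05 ± 0.03 in RAF1 cells, a difference of 6.61, or 4.66 with values under 4 set to 4 (SE 0.37, adjusted p = 0.000127). CD24 differed by −0.07 (adjusted p = 1). PYCARD kept its call with any of the 4 arrays left out, and lost it when only the arrays of these groups were fitted (adjusted p = 1), where 0 genes passed in limma.

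Estrogen response stood higher in lung metastasis by a mean of 0.72 over 27 genes, with 0 past the test over all genes and 2 higher when adjusted over the list alone (list adjusted p = 1.27e-07, adjusted p = 0.743 with an estimated correlation). Antigen presentation stood higher by 0.45 over 17 genes (list adjusted p = 0.0357, adjusted p = 0.744 with an estimated correlation), but its arrays overlapped, at 8.6 and 7.88 against 7.28 and 8.3 in RAF1. Cholesterol synthesis was lower by 0.54 over 19 genes (list adjusted p = 9.28e-06, adjusted p = 0.743 with an estimated correlation), with arrays that overlapped at 8.27 and 9.06 against 9.5 and 8.91. The p53 targets were lower by 0.31 over 22 genes (list adjusted p = 0.00136, adjusted p = 0.743 with an estimated correlation). Each of these 3 lists had 0 members past the test. Interferon response was not called (adjusted p = 0.322), and the lung metastasis arrays differed from each other, at 9.26 and 6.19, as did the RAF1 arrays, at 5.51 and 9.2. Lung epithelium markers were not called (adjusted p = 0.825), nor were leukocyte markers (adjusted p = 0.135). The centrosome, cytokine, endothelial, lung epithelium, and liver and gut lists had a median, mean and test that differed in sign.

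The fit of 14 arrays gave 3 genes, all higher. Without RAF1 array 1 or 2 the count was 4 or 2, and without lung metastasis array 1 or 2 it was 2 or 64. Unadjusted, 227 of 11153 genes lay under 0.05, fewer than that share of genes would give without any difference.

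Cells from visceral metastases had less TM4SF1 and more TGFB2 than RAF1 cells. TM4SF1, the membrane protein, was at 3.6 ± 0.51 against 13.04 ± 0.29, a difference of −9.44 (SE 1.3, adjusted p = 0.0465). TGFB2, a ligand of the TGF beta receptors, was at 8.65 ± 0.14 against 5.25 ± 0.5, a difference of 3.4 (SE 0.38, adjusted p = 0.0106). TCN1, a vitamin B12 binding protein, was at 7.21 ± 0.1 against 2.31 ± 0.03, a difference of 4.9 (SE 0.26, adjusted p = 3.89e-05). The nuclear envelope protein SYNE1 was higher by 4.55 (SE 0.24, adjusted p = 3.89e-05), the mitochondrial folate enzyme ALDH1L2 by 4.29, the interferon-induced TRIM22 by 4.11 and the serine protease PRSS23 by 2.38. CD24 differed by −0.11 (adjusted p = 1).

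Interferon response stood higher in visceral metastasis by a mean of 3.42 over 32 genes, with 0 past the test over all genes and 19 higher when adjusted over the list alone (list adjusted p = 1.38e-31, adjusted p = 0.276 with an estimated correlation). The visceral arrays were at 10.76 and 10.8, and the RAF1 arrays at 5.51 and 9.2. Antigen presentation stood higher by 1.59 over 17 genes, with 11 higher when adjusted over the list alone (list adjusted p = 6.71e-14, adjusted p = 0.112 with an estimated correlation). Inflammatory cytokines stood higher by 0.84 over 8 genes (list adjusted p = 0.00108, adjusted p = 0.112 with an estimated correlation), and the unfolded protein response by 0.59 over 23 (list adjusted p = 0.000409, adjusted p = 0.575 with an estimated correlation). Each of these 3 lists had 0 members past the test over all genes.

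Estrogen response stood higher in visceral metastasis by 0.43 over 27 genes (list adjusted p = 0.00207, adjusted p = 0.606 with an estimated correlation), and p53 targets by 0.31 over 22 (list adjusted p = 0.0193, adjusted p = 0.667 with an estimated correlation). Cell cycle genes were lower by 0.51 over 32 genes (list adjusted p = 0.00207, adjusted p = 0.699 with an estimated correlation), and immediate early genes were lower by 0.41 over 23 (list adjusted p = 0.00635, adjusted p = 0.565 with an estimated correlation). Hypoxia and glycolysis was lower by 0.18 over 32 genes (list adjusted p = 0.0356, adjusted p = 0.699 with an estimated correlation). Its arrays overlapped, at 9.53 and 9.58 against 9.56 and 9.91, and its call ended in the fit of 14 arrays (adjusted p = 0.156) and after median centring (adjusted p = 0.125). Lung epithelium markers stood higher by 1.08 over 4 genes (list adjusted p = 0.0278, adjusted p = 0.282 with an estimated correlation). That call ended in the fit of 14 arrays (adjusted p = 0.119), after median centring (adjusted p = 0.125) and without the filter (adjusted p = 0.477). In all of these lists 0 members passed over all genes.

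Mesenchymal transition had TGFB2 higher, 1 of 12, and was not called (adjusted p = 0.0927). Leukocyte markers were not called (adjusted p = 0.323). The ErbB, matrix, leukocyte, and liver and gut lists had a median, mean and test that differed in sign. Visceral metastasis against RAF1 gave 9 genes, 7 higher and 2 lower, and 296 in the fit of 14 arrays (138 higher, 158 lower). Quantile scaling gave 9 higher and 1 lower. Without RAF1 array 1 or 2 the count was 10 or 29, and without either visceral array it was 2. The call of TM4SF1 ended with any of these 4 arrays left out (adjusted p from 0.109 to 0.422). ALDH1L2, TRIM22, TGFB2 and PRSS23 lost their calls without visceral array 1 or 2 (adjusted p from 0.0779 to 0.201). TM4SF1 also did not pass without the filter (adjusted p = 0.0652), with a filter on a mean of 5 (adjusted p = 0.158) or without moderation (adjusted p = 0.134). Median centring ended the calls of ALDH1L2 (adjusted p = 0.0607) and TGFB2 (adjusted p = 0.0986), and fitting only the arrays of these groups ended those of ALDH1L2, TRIM22 and TGFB2 (adjusted p from 0.111 to 0.128).

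Against wild type cells, lung metastasis cells showed large differences at genes that RAF1 cells also carried, a resemblance that shares its wild type arrays. PLS3, the actin bundler, was at 11.88 ± 0.04 against 2.67 ± 0.11, a difference of 9.21 (SE 0.65, adjusted p = 2.42e-05). TM4SF1 was at 13.01 ± 0.87 against 4.03 ± 0.65, a difference of 8.97 (SE 1.3, adjusted p = 0.00215). CA2 differed by −10.6 (SE 0.46, adjusted p = 2.42e-06). The amino acid transporter SLC6A14 fell from 12.09 ± 0.12 to 3.25 ± 0.5, a difference of −8.84 (SE 0.57, adjusted p = 1.58e-05).

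The cytokine IL20 rose by 8.02, NUPR1 by 7.59 and the anthrax toxin receptor ANTXR1 by 6.01. The steroid-metabolising AKR1C2 fell by 8.54, the chloride channel CLIC3 by 8.03, the adhesion molecule CEACAM5 by 7.33 and S100A8 by 7.29. CD24 differed by −1.21 (adjusted p = 0.124) and passed with 14 arrays (adjusted p = 0.00476), array weights, the shared title prefix, median centring and quantile scaling (adjusted p from 0.000474 to 0.0107).

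Basal and stem cell markers fell at 6 of 14 in lung metastasis, rose at 0 and did not pass at 8, and the list kept its call both ways (adjusted p = 3.18e-06, adjusted p = 0.0238 with an estimated correlation). SOX2 changed by −6.59, NT5E by −5.36, ITGB4 by −3.26 and the metallopeptidase MME by −2.51. Adipocyte markers fell at 3 of 3, with a change in CD36 by −6.99, PPARG by −3.45 and ADIPOR2 by −1.32 (list adjusted p = 3.02e-05, adjusted p = 0.033 with an estimated correlation). Cholesterol synthesis fell at 5 of 19, rose at 0 and did not pass at 14, and 10 fell when adjusted over the list alone. LSS changed by −2.16, TM7SF2 by −1.93 and DHCR7 by −1.87 (list adjusted p = 3.02e-05, adjusted p = 0.601 with an estimated correlation).

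Ribosomal proteins rose at 9 of 27 in lung metastasis, fell at 0 and did not pass at 18, with RPL19 at 1.18, RPS9 at 1.12 and RPL3 at 1.12, the last not after median centring, where adjusted p = 0.106 (list adjusted p = 3.3e-08, adjusted p = 0.282 with an estimated correlation). Estrogen response fell at 8 of 27, rose at 2 and did not pass at 17, with AGR3 at −8.18 and AGR2 at −7.34 (list adjusted p = 0.0302, adjusted p = 0.698 with an estimated correlation). Interferon response fell at 2 of 32, PSMB8 by 4.89 and ISG20 by 4.66, with 0 higher (list adjusted p = 3.02e-05, adjusted p = 0.698 with an estimated correlation), and the lung metastasis arrays lay at 9.26 and 6.19. Antigen presentation fell at 2 of 17 with 0 higher (list adjusted p = 0.0137, adjusted p = 0.641 with an estimated correlation), and hypoxia and glycolysis at 6 of 32 with 0 higher (list adjusted p = 0.0129, adjusted p = 0.698 with an estimated correlation). Leukocyte markers fell at 2 of 4, with CORO1A at −5.31 (list adjusted p = 0.0196, adjusted p = 0.234 with an estimated correlation). Median centring ended that call (adjusted p = 0.0604), as did omitting the filter (adjusted p = 0.246). Matrix and protease genes fell at 5 of 23 with 0 higher (list adjusted p = 0.0302, adjusted p = 0.556 with an estimated correlation), a call that ended without the filter (adjusted p = 0.0647).

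The unfolded protein response was not called (adjusted p = 0.344), with 3 of 23 higher, among them the asparagine synthetase ASNS at 3.53 and ATF4 at 1.74. Lung epithelium markers had 0 of 4 in either direction (adjusted p = 0.941). ERK output and other lists were not called, and immediate early genes had a median, mean and test that differed in sign.

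Lung metastasis against wild type gave 1296 genes, 492 higher and 804 lower, and 4420 in the fit of 14 arrays (2272 higher, 2148 lower). After median centring the split was 835 higher and 927 lower. Without lung metastasis array 1 or 2 the count was 801 or 870, and without wild type array 1 or 2 it was 475 or 482. ADIPOR2 lost its call with any of these 4 arrays left out (adjusted p from 0.0891 to 0.218). The calls of ASNS, LSS and DHCR7 ended without lung metastasis array 1, wild type array 1 or 2 (adjusted p from 0.0916 to 0.164). RPL3 lost its call without wild type array 2 (adjusted p = 0.0632).

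Visceral metastasis cells were compared with wild type cells. NUPR1, a stress-induced chromatin cofactor, was at 14.11 ± 0.05 against 4.36 ± 0.02, a difference of 9.76 (SE 1.14, adjusted p = 0.000542). ASNS, which makes asparagine, was at 13.84 ± 0.01 against 9.47 ± 0.07, a difference of 4.37. CLDN1, a tight junction protein, was at 8.39 ± 0.01 against 2.81 ± 0.43, a difference of 5.58 (SE 0.53, adjusted p = 0.000146). CA2 differed by −10.57 (SE 0.46, adjusted p = 2.18e-06), and PYCARD stood at 2.02 ± 0.04, a difference of −7.59 (SE 0.37, adjusted p = 2.71e-06).

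The cytokines IL20 and TNFSF15 rose by 7.27 and 6.8, PLS3 by 9.33 and EHF by 6.11. MGP fell by 8.55, the actin-binding SYNPO2 by 8.3, SERPINA5 by 8.02 and the X-linked ARMCX1 by 7.57. CD24 differed by −1.25 (adjusted p = 0.104) and passed with 14 arrays (adjusted p = 0.00367), array weights, the shared title prefix, the groups of the contrast alone, median centring and quantile scaling (adjusted p from 1.43e-07 to 0.00945).

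The unfolded protein response rose at 6 of 23 genes in visceral metastasis, fell at 1 and did not pass at 16. The glutathione-degrading CHAC1 rose by 4, the transcription factor DDIT3 by 3.21 and SESN2 by 2.16. The list call at adjusted p = 0.0475 was lost (adjusted p = 0.786 with an estimated correlation), in the fit of 14 arrays (adjusted p = 0.161) and after median centring (adjusted p = 0.0917). Hypoxia and glycolysis fell at 12 of 32, rose at 0 and did not pass at 20, with the aldolase ALDOC at −3.07, ENO2 at −2.5 and NDRG1 at −2.45 (list adjusted p = 0.000425, adjusted p = 0.621 with an estimated correlation). Basal and stem cell markers fell at 7 of 14, rose at 0 and did not pass at 7 (list adjusted p = 0.000217, adjusted p = 0.0578 with an estimated correlation).

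Estrogen response fell at 8 of 27 in visceral metastasis, rose at 1 and did not pass at 18, with AGR2 at 10.16 ± 0.16, a difference of −4.71 (list adjusted p = 0.00572, adjusted p = 0.621 with an estimated correlation). Matrix and protease genes fell at 6 of 23, rose at 0 and did not pass at 17, with MMP16 at −5.15 and TIMP2 at −4.9 (list adjusted p = 0.0153, adjusted p = 0.504 with an estimated correlation). Ribosomal proteins rose at 9 of 27 and fell at 0, with RPL19 at 1.02 and RPL3 at 0.88, the latter not after median centring, where adjusted p = 0.147 (list adjusted p = 8.68e-06, adjusted p = 0.504 with an estimated correlation). Adipocyte markers fell at 2 of 3 (list adjusted p = 0.000392, adjusted p = 0.0578 with an estimated correlation).

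Interferon response was not called against wild type (adjusted p = 0.114), with a mean difference of 0.86 and 2 of 32 lower, PSMB8 at −4.87 and ISG20 at −2.77. Cell cycle had 6 of 32 lower, among them MYBL2 at −2.4 and E2F1 at −2.21, and was not called (adjusted p = 0.193). Mesenchymal transition had 2 of 12 higher and 2 lower, with TGFB2 at 4.43 and FN1 at −5.33 (adjusted p = 0.413). Leukocyte markers had the actin bundler LCP1 at 1.91 and CORO1A at −5.3 among 4 tested (adjusted p = 0.306). ERK output and other lists were not called, and those of liver and gut and of oxidative phosphorylation had a median, mean and test that differed in sign.

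Visceral metastasis against wild type gave 1547 genes, 542 higher and 1005 lower, and 4758 in the fit of 14 arrays (2232 higher, 2526 lower). After median centring the split was 1013 higher and 1039 lower. Without visceral array 1 or 2 the count was 579 or 611, and without wild type array 1 or 2 it was 574 or 601. The calls of SYNPO2, MYBL2, MMP16, NDRG1, CHAC1, DDIT3, SESN2, LCP1 and RPL3 ended with any of these 4 arrays left out (adjusted p from 0.0665 to 0.221). ALDOC lost its call without visceral array 2, wild type array 1 or 2 (adjusted p from 0.056 to 0.0622). The call of ASNS ended without wild type array 1 (adjusted p = 0.0514).

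Between the metastases, visceral cells had TGFB2 above lung cells, and TM4SF1 and PYCARD below them. TGFB2, the TGF beta ligand, was at 8.65 ± 0.14 against 3.93 ± 0.59, a difference of 4.72 (SE 0.38, adjusted p = 0.00084). PYCARD was at 2.02 ± 0.04 against 8.66 ± 0.89, a difference of −6.64, or −4.66 with values under 4 set to 4 (SE 0.37, adjusted p = 4.06e-05). TM4SF1 was at 3.6 ± 0.51 against 13.01 ± 0.87, a difference of −9.4 (SE 1.3, adjusted p = 0.0217). TCN1 was higher by 4.83 (SE 0.26, adjusted p = 3.85e-05), SYNE1 by 4.55, ALDH1L2 by 5.15, the growth factor FGF13 by 4.96, TRIM22 by 4.25, the antiviral RSAD2 by 4.18 and LCP1 by 3.49. The palmitoyltransferase ZDHHC2 was lower by 3.03, the zinc finger SALL2 by 2.61, NXN by 2.41 and FN1 by 1.59, and CD24 differed by −0.04 (adjusted p = 1).

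Interferon response had 1 of 32 higher, RSAD2, and a mean difference of 3.05, with 13 higher when adjusted over the list alone (list adjusted p = 1.48e-24, adjusted p = 0.264 with an estimated correlation). The visceral arrays lay at 10.76 and 10.8, and the lung arrays at 9.26 and 6.19. Antigen presentation had 1 of 17 higher, the class I activator NLRC5 at 2.68, and a mean difference of 1.13 (list adjusted p = 1.43e-08, adjusted p = 0.225 with an estimated correlation). Cholesterol synthesis stood higher by 0.9 over 19 genes (list adjusted p = 6.17e-06, adjusted p = 0.507 with an estimated correlation), p53 targets by 0.62 over 22 (list adjusted p = 6.89e-06, adjusted p = 0.287 with an estimated correlation) and the unfolded protein response by 0.35 over 23 (list adjusted p = 0.0171, adjusted p = 0.747 with an estimated correlation). The last of these ended without the filter (adjusted p = 0.052), and its difference came from lung array 2 at 10.04, as lung array 1 at 10.7 lay beside the visceral arrays at 10.71 and 10.74. Inflammatory cytokines were called higher with 0 of 8 past the test and 3 when adjusted over the list alone (list adjusted p = 0.00555, adjusted p = 0.225 with an estimated correlation).

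Cell cycle genes were lower in visceral than in lung metastasis by 0.56 over 32 genes, 0 of them past the test (list adjusted p = 0.00379, adjusted p = 0.796 with an estimated correlation). Hypoxia and glycolysis was lower by 0.28 over 32, also with 0 past the test (list adjusted p = 0.0171, adjusted p = 0.747 with an estimated correlation). Immediate early genes were lower by 0.5, with 1 of 23, IER3, past the test at −1.27 (list adjusted p = 0.0171, adjusted p = 0.598 with an estimated correlation). That call ended in the fit of 14 arrays (adjusted p = 0.092) and after median centring (adjusted p = 0.0639). ERK pathway output was lower by 0.51, with 1 of 20 past the test, again IER3 (list adjusted p = 0.0221, adjusted p = 0.225 with an estimated correlation), and the call ended in the fit of 14 arrays (adjusted p = 0.0837).

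Lung epithelium markers stood higher in visceral metastasis by 1.06 over 4 genes (list adjusted p = 0.0171, adjusted p = 0.226 with an estimated correlation). The call ended in the fit of 14 arrays (adjusted p = 0.0696), after median centring (adjusted p = 0.119) and without the filter (adjusted p = 0.325). Leukocyte markers had 1 of 4 higher, LCP1, and were not called (adjusted p = 0.0788). The ErbB, epithelial junction, matrix, endothelial, and liver and gut lists had a median, mean and test that differed in sign.

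**Figure D3:**
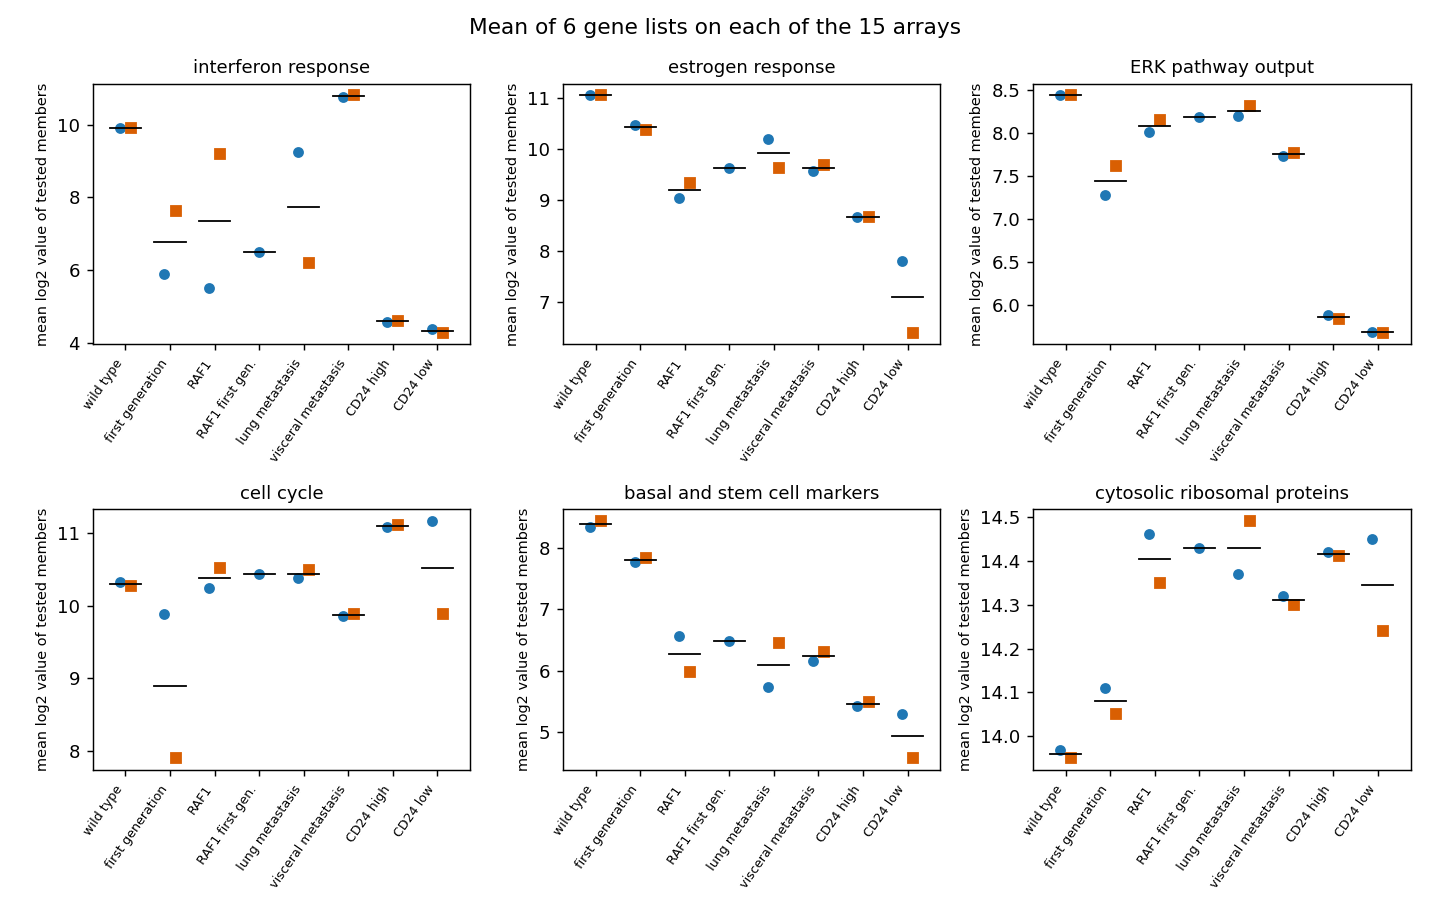
Mean log2 expression of 6 gene lists on each array.

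Visceral against lung metastasis gave 35 genes, 18 higher and 17 lower, and 506 in the fit of 14 arrays (210 higher, 296 lower). The split was 25 higher and 10 lower after median centring and 16 higher and 8 lower after quantile scaling. Without lung metastasis array 1 or 2 the count was 33 or 128, and without visceral array 1 or 2 it was 6 or 8. TM4SF1, NXN and FN1 lost their calls with any of these 4 arrays left out (adjusted p from 0.0545 to 0.319). The calls of LCP1, SALL2 and IER3 ended without lung metastasis array 1, visceral array 1 or 2 (adjusted p from 0.125 to 0.319). NLRC5 lost its call without lung metastasis array 1, lung metastasis array 2 or visceral array 1 (adjusted p from 0.0545 to 0.264). The call of RSAD2 ended without lung metastasis array 2, visceral array 1 or 2 (adjusted p from 0.0613 to 0.311). FGF13, TRIM22 and ZDHHC2 lost their calls without visceral array 1 or 2 (adjusted p from 0.0818 to 0.249). With only the arrays of these groups fitted, 16 of the 20 named calls ended (adjusted p from 0.0528 to 0.137), and of the named genes here only TCN1, SYNE1, ALDH1L2 and FGF13 passed. Median centring ended 10 of the 20, among them RSAD2, LCP1, ZDHHC2, SALL2, NXN, FN1, IER3 and NLRC5 (adjusted p from 0.0557 to 0.319), and quantile scaling ended 9, the same genes here except RSAD2 (adjusted p from 0.0514 to 0.122).

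CD24 low cells were compared with CD24 high cells, where CD24, the glycoprotein that defines the groups, stood at 10.4 ± 1.13 and 12.29 ± 0.04. Its difference of −1.9 (SE 0.45) did not pass (adjusted p = 0.252), except without CD24 low array 1 (adjusted p = 4.79e-05), and is no finding. PGR, the progesterone receptor induced by estrogen, fell from 8.26 ± 0.08 to 3.73 ± 0.61, a difference of −4.53 (SE 0.39, adjusted p = 0.00778). EGR3, an immediate early transcription factor, fell from 8.49 ± 0.2 to 4.43 ± 0.66, a difference of −4.05 (SE 0.38, adjusted p = 0.00786). The plexin PLXNB1 also fell, by 2.72 (adjusted p = 0.00954), below the level asked of named genes at 5.51 in CD24 high cells, and added after the values were seen.

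Estrogen response genes fell at 1 of 27, PGR, rose at 0 and did not pass at 26, and 14 fell when adjusted over the list alone. The median difference was −2.01 and the mean −1.56 (list adjusted p = 0.00369, adjusted p = 0.854 with an estimated correlation). The list means were 8.67 and 8.67 in CD24 high cells against 7.81 and 6.41 in CD24 low cells. ERK pathway output had 1 of 20 lower, EGR3, and 4 lower with 1 higher when adjusted over the list alone (adjusted p = 0.588). Immediate early genes had 1 of 23 lower, again EGR3 (adjusted p = 0.934). Basal and stem cell markers were not called (adjusted p = 0.52), nor was mesenchymal transition (adjusted p = 0.548), each with 0 past the test.

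CD24 low array 2 had an upper quartile of 5.95, against 7.06 to 7.27 on the other arrays, and 32.6% of probe sets at 5 or more, against 36.3% to 38.3%. Over all tested genes the median difference was −0.441, and −0.01 after quantile scaling, so 14 lists had a median, mean and test that differed in sign. These were the ERK, ErbB, basal, mesenchymal, junction, cell cycle, interferon, antigen presentation, cytokine, matrix, unfolded protein response, endothelial, adipocyte and ribosomal lists.

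CD24 low against CD24 high gave 4 genes, 1 higher and 3 lower, and 11 in the fit of 14 arrays (4 higher, 7 lower), where CD24 low is 1 array. The split was 0 higher and 5 lower after median centring and 0 higher and 4 lower after quantile scaling. Without CD24 high array 1 or 2 the count was 0, without CD24 low array 1 it was 6959 and without CD24 low array 2 it was 11. PGR lost its call without CD24 high array 1 (adjusted p = 0.116) or 2 (adjusted p = 0.0997), and so did EGR3 (adjusted p = 0.116 and adjusted p = 0.132). Both were also lost with array weights (adjusted p = 0.924) and with the CD24 arrays fitted alone (adjusted p = 0.677), where limma gave 0 genes. Unadjusted, 1935 genes lay under 0.05 in the fit of all arrays.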

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

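The tests below were chosen only after the results they weigh had been seen, except the test on neighbouring genes.

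The difference between cells with and without RAF1 was itself different between first generation and original cells at 149 genes, with 107 more positive and 42 more negative in first generation cells. The difference from RAF1 cells was different between visceral and lung metastasis at 35 genes, with 18 higher and 17 lower in visceral metastasis.

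RAF1 cells differed from wild type at 1320 genes. DNA copy number of a diverged sub-line stays open. Windows of neighbouring genes that shifted together held 13.6% of genes called, 179 of 1316, and 7.5% of all placed. Shifts of log2 1 were seldom called in simulated data, so this cannot decide. A fault of the RAF1 or wild type arrays was argued against by the first generation pair, which shared no array with them and gave a correlation of 0.64 across genes. Whether the introduced RAF1 cDNA alone explains the differences cannot be told apart from a difference between sub-lines, because CD24 high cells lay nearer wild type at 13.7% of those genes, or 23.3% of the 4336 genes of the 14 arrays, and the labels do not say whether they carry RAF1. It stays open how long the cells were grown apart and whether RAF1 cells were selected.

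CD24 low array 2 stood apart from the other 14 arrays. A fault of hybridisation or scanning of that array is a possible explanation. Of its spike-in probe sets, 72.2%, 13 of 18, lay outside the range of the other arrays, all of them below it. A change that belongs to CD24 low cells was argued against by CD24 low array 1, which departed the same way at 3.5% of the genes, 216 of 6234. Its cause stays open.

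Interferon genes stood higher on the visceral metastasis arrays than on the RAF1 and lung metastasis arrays. A difference between cultures or arrays of a single group could produce this, as the gap between the RAF1 arrays, 3.69, was 1.08 times the difference of 3.42 between visceral metastasis and RAF1. Leukocytes among the cells were argued against, with 0 of 17 leukocyte markers that were low in wild type reaching log2 5 on both visceral arrays, a set without LCP1, which was at 8.81 in wild type and 10.71 in visceral cells. Mouse leukocytes would be seen by these human probes only through cross-hybridisation, so mouse cells stay open, as does the cause of the gap within RAF1.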

How the results depend on the processing

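Small groups and signal near background limited the results. Each group had 1 or 2 arrays, and the median SE of RAF1 against wild type was 0.44 with 15 arrays and 0.22 with the 14 arrays that leave out CD24 low array 2. In simulated data for RAF1 against wild type, 7.5% of genes with a log2 difference of 1 were recovered with 15 arrays and 53.7% with 14. No paired analysis was possible because the labels give no replicate numbers. Of 422 calls of named genes, 0 reversed direction under any alternative. CD24, named by rule, gained a call in 4 comparisons with 14 arrays. The number of calls lost was 70 after median centring, 29 after quantile scaling, 116 with the groups of the contrast alone and 50 without moderation. Of 83 list calls, 4 held with an estimated correlation, 34 with the fry test, 73 with 14 arrays, 73 after median centring and 77 without the filter. Counts of genes stayed within 1.5 times, apart from those below, and where no reason is given the cause was not tested.

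The fit of 14 arrays, chosen after the data were seen, gave 4336 genes for RAF1 against wild type, 2236 for first generation against wild type, 3717 for RAF1 first generation against first generation and 934 for the interaction. It gave 23 for RAF1 first generation against RAF1, 3 for lung metastasis against RAF1 and 296 for visceral metastasis against RAF1. Lung and visceral metastasis against wild type gave 4420 and 4758, visceral against lung metastasis 506, and CD24 low against high 11.

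Array weights gave 4714 for RAF1 against wild type, 1810 for first generation against wild type, 3756 for RAF1 first generation against first generation and 1114 for the interaction. They gave 163 for RAF1 first generation against RAF1, 3 for lung metastasis against RAF1, 870 for visceral metastasis against RAF1, 4234 and 7593 for lung and visceral metastasis against wild type, 773 for visceral against lung metastasis and 0 for CD24 low against high. The arrays of a shared title prefix alone gave 3747, 1606, 3066 and 464 in the first 4 of these. They gave 2 for lung metastasis against RAF1, 44 for visceral metastasis against RAF1, 3821 and 4230 for lung and visceral metastasis against wild type, 195 for visceral against lung metastasis and 0 for CD24 low against high.

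The groups of the contrast alone gave 3767 for RAF1 against wild type, 729 for first generation against wild type, 0 for RAF1 first generation against first generation and 0 against RAF1. Lung metastasis against RAF1 gave 0, lung and visceral metastasis against wild type 3188 and 7383, visceral against lung metastasis 9, and CD24 low against high 0.

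Every probe set tested on its own, which counts a gene more than once, gave 2251 for RAF1 against wild type, 661 for first generation against wild type and 1418 for RAF1 first generation against first generation. It gave 25 for visceral metastasis against RAF1, 2309 and 2771 for lung and visceral metastasis against wild type, 63 for visceral against lung metastasis and 11 for CD24 low against high. The mean of a gene's probe sets gave 14 for visceral metastasis against RAF1 and 7 for CD24 low against high.

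A filter on a mean of 5, which tests fewer genes, gave 871 for RAF1 against wild type, 165 for first generation against wild type, 549 for RAF1 first generation against first generation, 30 for the interaction, 1 for RAF1 first generation against RAF1, 1 for visceral metastasis against RAF1 and 13 for visceral against lung metastasis. No filter gave 251 for the interaction, 50 for RAF1 first generation against RAF1, 4 and 22 for lung and visceral metastasis against RAF1, 55 for visceral against lung metastasis and 36 for CD24 low against high.

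Median centring gave 71 for the interaction and 1 for RAF1 first generation against RAF1, where quantile scaling also gave 1. Without moderation RAF1 first generation against RAF1 gave 14, lung metastasis against RAF1 3 and visceral metastasis against RAF1 16. With values under 4 set to 4 these gave 20, 2 and 25. Without the trend and robust options lung metastasis against RAF1 gave 2.

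Leaving out each array in turn gave 490 to 782 genes for RAF1 against wild type, 134 to 371 for first generation against wild type, 588 to 853 for RAF1 first generation against first generation and 71 to 208 for the interaction. RAF1 first generation against RAF1 ranged from 2 to 3, lung metastasis against RAF1 from 2 to 64 and visceral metastasis against RAF1 from 2 to 29. Lung metastasis against wild type ranged from 475 to 870, visceral metastasis against wild type from 574 to 611, visceral against lung metastasis from 6 to 128 and CD24 low against high from 0 to 6959.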

Other observations

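Gene families, grouped by the stem of the symbol, were tested with the Fisher test over 364 families per direction, a grouping added after the data were seen. Ribosomal protein genes of the large subunit were higher in RAF1 than in wild type cells at 13 of 39 (adjusted p = 1.65e-06). The test takes genes as independent, and the ribosomal list lost its call with an estimated correlation (adjusted p = 0.365), as did RPL3 and RPL14 after median centring (adjusted p = 0.121 and adjusted p = 0.175). Ephrin receptors of the A class, which guide cell contact, were lower in RAF1 cells at 5 of 6 tested (adjusted p = 0.00485). Keratins, the intermediate filaments of epithelia, were lower in RAF1 cells at 7 of 15 (adjusted p = 0.00904), namely KRT13, KRT15, KRT18, KRT19, KRT20, KRT23 and KRT80. Beta tubulins were lower in visceral metastasis than in wild type at 5 of 6 (adjusted p = 0.0119). The families were not tested with arrays left out.

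Windows of 40 neighbouring genes were also compared. On chromosome 8, the window from ZNF596 to PDGFRL had a median difference of 1.34 in lung metastasis against RAF1, 1.22 in lung metastasis against wild type and 1.35 in RAF1 first generation against first generation. In visceral against lung metastasis it was −1.2, and in first generation against wild type −0.53. Whether DNA copy number differed there was not resolved, as no DNA was measured. ZDHHC2, named in visceral against lung metastasis, lies in this window, and FN1 in a window on chromosome 2 that shifted by −0.39, so the doubt extends to them. In RAF1 against wild type JUNB and IER2 lay in a window at 0.76. The window from TAF4 to TCEA2 on chromosome 20 had −1.42 in RAF1 first generation against first generation. In first generation against wild type, 37 of 270 windows shifted.

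RAF1 array 1 correlated most with lung metastasis array 2, at 0.995, and 299 genes differed 2-fold between them. Between RAF1 arrays 1 and 2 the correlation was 0.989 and 884 genes differed 2-fold. Whether labels were exchanged or cultures differed was not resolved, and this doubt bears on every RAF1 and lung metastasis value. PYCARD ran with the labels, but it was named because it separated these groups, so it cannot weigh on this doubt.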
